A study of Mus musculus with 6 samples.

How the data were processed

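RNA was extracted with a phenol-based reagent from bone marrow CD34-negative KSL cells of WT and Elovl6 KO mice, and libraries were made with a strand-marking RNA library kit, per the labels' protocols. The genome build is mm10, per the submitters' processing notes. The aligner, the counting software, its use of strand and the sequencing machine are not given in the sources used here. The authors deposited 1 table of 51826 genes with a set of columns for each of the 6 libraries, each named in its header by genotype and number, and the columns were matched to libraries by those names.

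Per the file headers, the authors' expression values are read counts per gene. Every one of these values (100%) equals the unique exon reads plus the exon junction reads not placed uniquely, and the values are whole numbers. The deposited table also gives counts of unique and total exon reads, junction reads, intron reads and gene reads, RPKM values as the authors computed them, and a normalized signal that the authors' tool made from the expression values. The deposited normalized signal has the same sorted values in every library (largest difference 0), so it is quantile normalized and was not tested. RPKM from the authors was used only to work out the mapped reads per library. The authors deposited p-values, adjusted p-values and a signed fold from a test that the header names EDGE with tagwise dispersions, positive where KO is higher. Exon length was deposited too, and is 0 for 18706 genes. A further 30 per-library value columns were not used. Positions in the table count from 0 and were raised by 1. Of the gene IDs, 51633 were found in the GENCODE M21 reference, of which 47429 had the same symbol and 48626 the same position.

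Expression counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with filterByExpr on genotype, TMM factors and the quasi-likelihood F test with genotype as the only term over all 6 libraries. Benjamini-Hochberg adjustment covered the 11969 genes kept, at a threshold of 0.05. CPM values use TMM-scaled library sizes, and the SE of a log2 fold change is its size over the square root of F. Where a group had 0 counts, the fold is a lower bound against 3 counts over that group. With 1 to 3 counts a ratio with an exact 95% interval is given, which covers counting error only. Setting such members at their bounds left every list median as it was.

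Before the data were examined, 34 gene lists were fixed from general knowledge, of which 33 were tested and that of Y-linked genes and Xist served as a sample check. The lists cover HSC identity, multipotent and lymphoid-primed progenitors, markers of the other blood lineages and of stroma, lipid pathways, homing, signalling, cell cycle, translation, metabolism and stress. They were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists, and a list needed 5 measured members. An estimated correlation and fry were alternatives. Of the symbols, 2 were not matched in the table.

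The rule for named genes, also fixed before the data were examined, took Elovl6 and the other Elovl genes. It took the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold whose WT and KO libraries do not overlap, with a mean of at least 1 CPM and no predicted or clone name, Y-linked gene or Xist. Where fewer than 24 passed, it added the genes with the smallest p up to 24. It also took the 4 members of each list with the smallest p, and Cxcr4, Pik3cg, Rac2, Itgam and Itgb2. H2-K1, H2-D1, the other antigen presentation genes, CT010467.1 and the immunoglobulin V genes outside this rule were chosen after their values were seen. A gene among those past the threshold is not reported here. WT and KO libraries did not overlap in 2428 genes (20.3%), where chance gives 13.3%.

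Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test (its lists with camera on the Wald statistics), limma-voom with sample quality weights, no filter, a filter at a mean of 5 CPM, each library left out in turn, the replicate number as a block in the 4 libraries numbered 1 and 2, and glmTreat against a fold of 1.5. A sex covariate was not fitted because all libraries had Y-linked counts and none of Xist, and a pseudocount alternative does not apply to counts. After the data were seen, unique exon reads, total exon reads and the removal of KO replicates 3 and 4 together were added. Tables were prepared with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

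The test was tried on 5 simulations of 11969 genes drawn from the real means and library sizes. It called 38.5% of genes changed 2-fold, 80.3% of those changed 4-fold and 94.2% of those changed 8-fold, and 7.56% of its calls were unchanged genes. Over the 5 runs 335, 335 and 330 genes were changed 2-, 4- and 8-fold. The share of unchanged genes among the calls depends on these numbers, so it does not carry over to the calls in the data. A list of 30 genes shifted by 0.5 log2 was called in 5 of 5 runs and 0 of 165 unchanged lists were. Genes were drawn independently of each other, so these runs do not test the preset correlation. In the data the estimated correlation was 0.65 for immediate early genes, 0.48 for cytosolic ribosomal proteins and 0.39 for HSC identity. It ran from -0.03 to 0.88 over the lists. A scan of gene positions found a planted group of 10 genes in 10 of 10 runs and called none of 10 runs without one.

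Counts assigned to genes ranged from 2121240 to 5137628 per library, 18.4% to 33.8% of the mapped reads. No 2 libraries agreed within sampling noise (chi-square per degree of freedom 6.23 to 20.6). The first principal component of the 500 most variable genes (41.1% of variance) set KO replicate 4 apart and the second (27.2%) separated the genotypes.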

Results

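Gene expression was measured by RNA sequencing in CD34-negative KSL cells of mouse bone marrow, the Kit-positive, Sca-1-positive, lineage-negative fraction that is enriched for long-term hematopoietic stem cells. The series has 2 libraries from wild-type (WT) mice and 4 from mice lacking Elovl6 (KO), the enzyme that lengthens fatty acids of the palmitate class to those of the stearate class. Counts assigned to genes totalled 3569449 and 3812524 in WT replicates 1 and 2, and 5137628, 4720822, 2816248 and 2121240 in KO replicates 1 to 4. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries only. Xist had 0 counts in all 6 libraries and the Y-linked gene Ddx3y had between 107 and 349, so no library stood apart by sex. The comparison asks how loss of Elovl6 changes gene expression of these stem cells.

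In KO cells, Gbp2b and several genes of the histocompatibility region on chromosome 17 were read at levels next to absent in WT, and the AP-1 gene Fosb rose about 5.13-fold. Iglc2, Iglv2, Ighv10-1, Gm2a, Rec8, Rpl34 and Rpl21 fell. As lists, immediate early genes were higher, and ribosomal protein genes and HSC identity genes lower, in KO at a preset correlation between genes, but 0 lists passed with an estimated one.

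Elovl6 itself (ENSMUSG00000041220, chromosome 3, 129532355 to 129638495, mm10) was at 34.4 ± 5.5 CPM in WT (SD, n = 2) and 15.6 ± 5.9 CPM in KO (SD, n = 4). Its counts were 111 and 147 in the WT libraries and 106, 61, 56 and 18 in KO replicates 1 to 4. No KO library reached the WT level, since the highest KO value was 21.4 CPM and the lowest WT value 30.6 CPM. The log2 fold change of -1.12 (SE 0.32) did not pass the genome-wide threshold (adjusted p = 0.346, edgeR quasi-likelihood test). In the authors' deposited table the gene has a signed fold of -2.18 and an adjusted p of 0.426. Reads counted over a whole gene check little where only a part of it was removed, and the labels do not give the part. Of the other elongases, Elovl1 was at -0.43 (SE 0.19, adjusted p = 0.494), Elovl5 at 0.16 (SE 0.16, adjusted p = 0.771) and Elovl7 at 0.73 (SE 0.60, adjusted p = 0.719) on the log2 scale, none past the threshold.

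Across the genome (edgeR quasi-likelihood test), 19 of 11969 tested genes differed between KO and WT, 11 higher and 8 lower in KO. The genes that rose by the widest margins were read in KO and next to absent in WT. Gbp2b, a guanylate-binding protein gene (ENSMUSG00000040264, chromosome 3, 142594847 to 142619179), had 0 counts in both WT libraries and 1248 in the 4 KO libraries. It was at 85.5 ± 5.0 CPM (SD, n = 4) in KO, which is at least 212-fold higher when 3 counts over the WT group are taken as the floor. The class II gene H2-Ea-ps (at least 39.9-fold), a polymorphic pseudogene in the annotation like H2-Bl, was likewise at 0 counts in WT. The class I histocompatibility genes H2-Q10, H2-Q2 and H2-Bl had 2 counts each in WT, with ratios of KO to WT of 102 (95% counting interval 28.1 to 847), 79.3 (21.8 to 657) and 34.4 (9.34 to 287). These intervals cover counting error only. Msh5, a meiotic recombination gene, rose by 3.86 (log2, SE 0.58), and Lyrm7, an assembly factor of the respiratory chain, by 2.33 (SE 0.36). Fosb, an AP-1 transcription factor, rose by 2.36 (SE 0.29), the interleukin-10 receptor gene Il10ra by 1.28 (SE 0.19) and the integrin gene Itgb5 by 1.17 (SE 0.19). Adjusted p-values of the risen genes ran from 5.4e-06 to 0.0444 (edgeR quasi-likelihood test).

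Of the genes that fell, 3 encode immunoglobulin chains. Iglc2 was at 94.8 ± 34.9 CPM in WT (SD, n = 2) and 2.57 ± 2.78 CPM in KO (SD, n = 4). Iglv2 had 182 counts in WT against 2 in KO and Ighv10-1 had 100 against 1. These are ratios of WT to KO of 179 (95% counting interval 48.7 to 1485) and 196 (34.4 to 7824). The meiotic cohesin gene Rec8 fell by 1.91 (SE 0.26) and the ganglioside activator gene Gm2a by 1.64 (SE 0.20). The ribosomal protein genes Rpl34 and Rpl21 fell by 1.20 (SE 0.11) and 0.85 (SE 0.13), and the linker histone gene H1f0 by 0.85 (SE 0.13) on the log2 scale. Rpl34 went from 1214 ± 118 CPM in WT (SD, n = 2) to 529 ± 18 CPM in KO (SD, n = 4). Genes next in rank that did not pass were Rftn2 at 2.63 (adjusted p = 0.0518), Fos at 1.22 (adjusted p = 0.0707), Cdkn1a at 2.27 (adjusted p = 0.0707), Anks1 at -0.81 (adjusted p = 0.0947) and Dusp1 at 1.08 (adjusted p = 0.109).

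**Figure D1:**
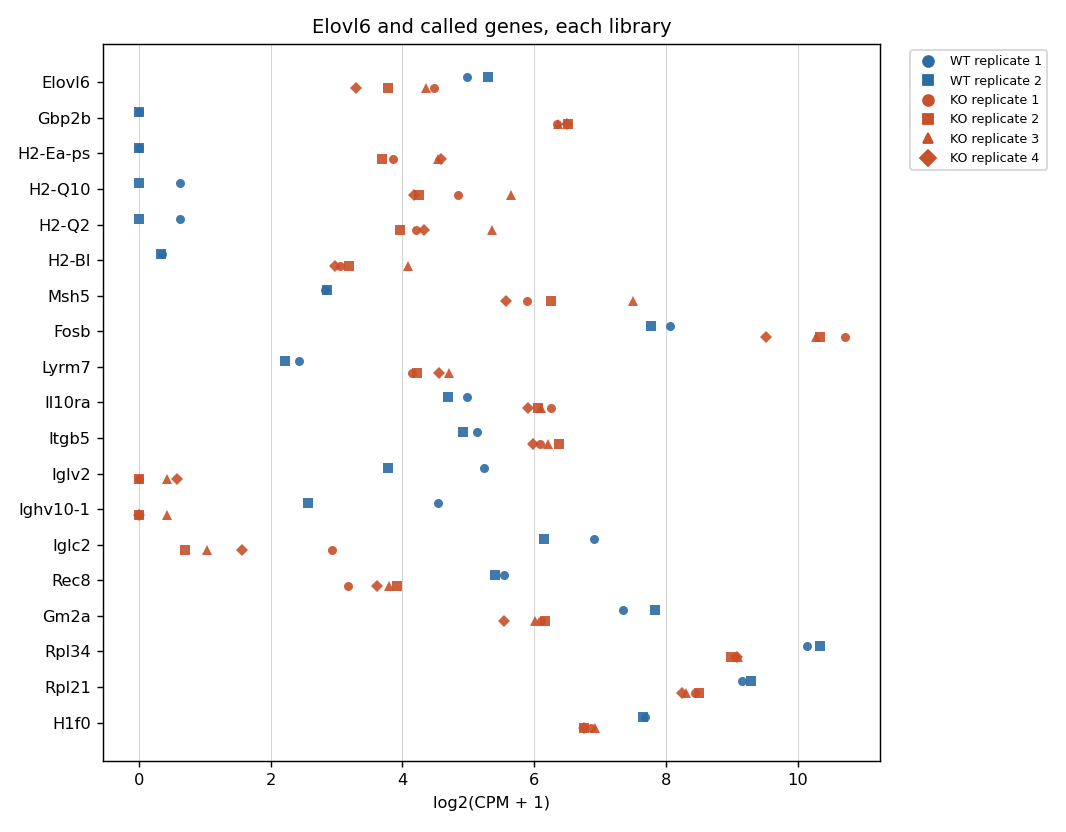
Expression of Elovl6 and of the called genes named in the text in each library, on an axis of log2(CPM + 1), with WT in blue, KO in orange and the marker giving the replicate. Each called gene plotted separates the WT from the KO libraries, and Gbp2b and H2-Ea-ps lie at 0 in WT.

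Of the called genes, 5 lie on chromosome 17 between 34.3 and 36.1 Mb (mm10), in the histocompatibility region: H2-Ea-ps, Msh5, H2-Q2, H2-Q10 and H2-Bl. H2-K1 and H2-D1, the main class I genes there, were at -1.01 (SE 0.24, adjusted p = 0.241) and -0.39 (SE 0.12, adjusted p = 0.372). Between 25 and 40 Mb of that chromosome, 29 genes had an unadjusted p under 0.01, 19 higher and 10 lower in KO. Counts of several called genes rest in part on junction reads that also map elsewhere. Reads placed uniquely made up 22.8% of the total exon reads of Rpl21, 42.7% of Rpl34 and 53.2% of H2-Q10. These are not shares of the tested counts, which leave out multi-mapping exon reads that cross no junction. H2-Q10 was at 6.54 in the main test and at 6.42 with unique exon reads alone. Rpl34 was at -2.18 with unique exon reads alone and at -1.03 with multi-mapping ones included, so the size of its fall depends on the reads counted. It lost the call with the replicate number as a block (adjusted p = 0.079). With multi-mapping exon reads included, H2-Q10 was at 2.65 on the log2 scale and lost the call (adjusted p = 0.130). Msh5, Lyrm7 and Itgb5 also missed the threshold there (adjusted p = 0.0543, 0.055 and 0.0625), but at log2 fold changes of 3.86, 2.33 and 1.18, and 96% to 100% of their exon reads were placed uniquely.

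**Figure D2:**
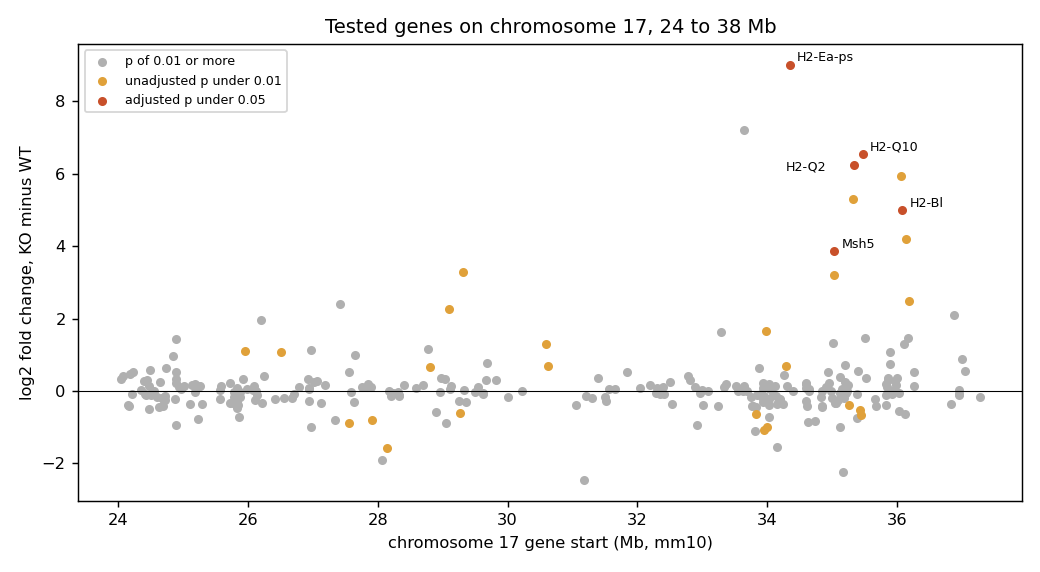
Log2 fold change (KO minus WT) of each tested gene against its start on chromosome 17 in Mb (mm10), coloured by its p. The 5 called genes lie between 34.3 and 36.1 Mb and all are higher in KO, while genes at an unadjusted p under 0.01 lie on both sides of 0, and fitted values of genes with few WT counts depend on the prior count.

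The count of called genes depended on single libraries. It was 2 without WT replicate 1, 10 without WT replicate 2, 12 without KO replicate 2, 11 without KO replicate 3 and 30 without KO replicate 4. Of the 19 genes, 2 kept the call without WT replicate 1 and 6 without WT replicate 2. Libraries of KO replicates 3 and 4 had the highest share of mapped reads on CT010467.1, a ribosomal RNA-like gene, at 22.0% and 27.9% against 11.4% to 14.8% in the other 4. Without both, 33 genes were called, 28 higher and 5 lower, of which 11 were among the 19. Gbp2b passed under each of the 16 alternatives. The authors' deposited table has 76 genes at an adjusted p under 0.05, and all 19 are among them.

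Gene lists fixed before the data were examined were then compared. Of 33 lists, 13 passed the camera test, 8 upward and 5 downward. With an estimated correlation 0 lists passed in camera (smallest adjusted p = 0.633), and 0 had an unadjusted p under 0.05. The fry test, which asks whether a list moves on balance one way, gave 0 lists (smallest adjusted p = 0.146), and 2 had an unadjusted p under 0.05. Every direction named for a list in the following rests on the preset correlation. Of the 13 lists, 3 passed without each library in turn (immediate early genes, cytosolic ribosomal proteins and HSC identity) and 10 did not.

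Immediate early genes, the transcription factors and feedback regulators quickly induced by a stimulus, rose as a list. Of these, 24 of 26 measured members were above 0, with a median log2 fold change of 0.82 (camera adjusted p = 1e-10, adjusted p = 0.633 with an estimated correlation). Over all genes, 1 member, Fosb, passed in edgeR, DESeq2 called 9, limma-voom 0, and 15 passed when adjusted over the list alone. Fosb missed the threshold with limma-voom (adjusted p = 0.174), without WT replicate 1 (0.308) and without WT replicate 2 (0.329), at log2 fold changes of 2.30, 2.51 and 2.22. Fosb stood at 242 ± 34 CPM in WT (SD, n = 2) and 1239 ± 389 CPM in KO (SD, n = 4), Fos at 1395 ± 57 and 3252 ± 784 CPM, Jund at 191 ± 31 and 326 ± 23 CPM, and Dusp1, a MAP kinase phosphatase, at 349 ± 13 and 740 ± 168 CPM. The list scores were 0.70 and 0.66 in KO replicates 1 and 2, and -0.41 and -0.72 in WT replicates 1 and 2. They were -0.02 and -0.21 in KO replicates 3 and 4, the libraries with most ribosomal RNA-like reads.

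Cell cycle inhibitors and quiescence genes also rose as a list (22 of 31 above 0, median 0.21, camera adjusted p = 0.00818, adjusted p = 0.633 with an estimated correlation). In edgeR 0 members passed over all genes, 12 had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 0. Adjusted over the list alone, 9 were higher, such as Klf6, Klf4 and the cell cycle inhibitor Cdkn1a, and 2 lower. Txnip, also a member of the HSC identity list, was among the lower ones (log2 fold change -0.94). The list of cell cycle inhibitors and quiescence genes shares 6 genes with the immediate early list. Without these its median was 0.12 and its camera test gave an unadjusted p of 0.167. Without WT replicate 2 its median was 0.21 and its camera adjusted p = 0.194. The p53 target and apoptosis list rose (23 of 34 above 0, median 0.19, camera adjusted p = 0.0308, adjusted p = 0.633 with an estimated correlation). Of its members 0 passed over all genes, 5 had an unadjusted p under 0.05, DESeq2 called 1, limma-voom 0, and 2 rose when adjusted over the list alone. The p53 median was 0.17 without KO replicate 1 (camera adjusted p = 0.0797) and 0.18 without WT replicate 1 (camera adjusted p = 0.456). The inflammatory and NF-kB list rose (17 of 31 above 0, median 0.08, camera adjusted p = 0.0463, adjusted p = 0.633 with an estimated correlation). Of its members 0 passed over all genes, 10 had an unadjusted p under 0.05, DESeq2 called 4, limma-voom 0, and 7 rose when adjusted over the list alone. The NF-kB median was 0.099 without KO replicate 1, 0.088 without KO replicate 2 and 0.059 without WT replicate 2 (camera adjusted p = 0.174, 0.220 and 0.561). Its median was 0.16 without KO replicate 3, 0.046 without KO replicate 4 and 0.24 without WT replicate 1 (camera adjusted p = 0.011, 0.0131 and 0.0129).

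**Figure D3:**
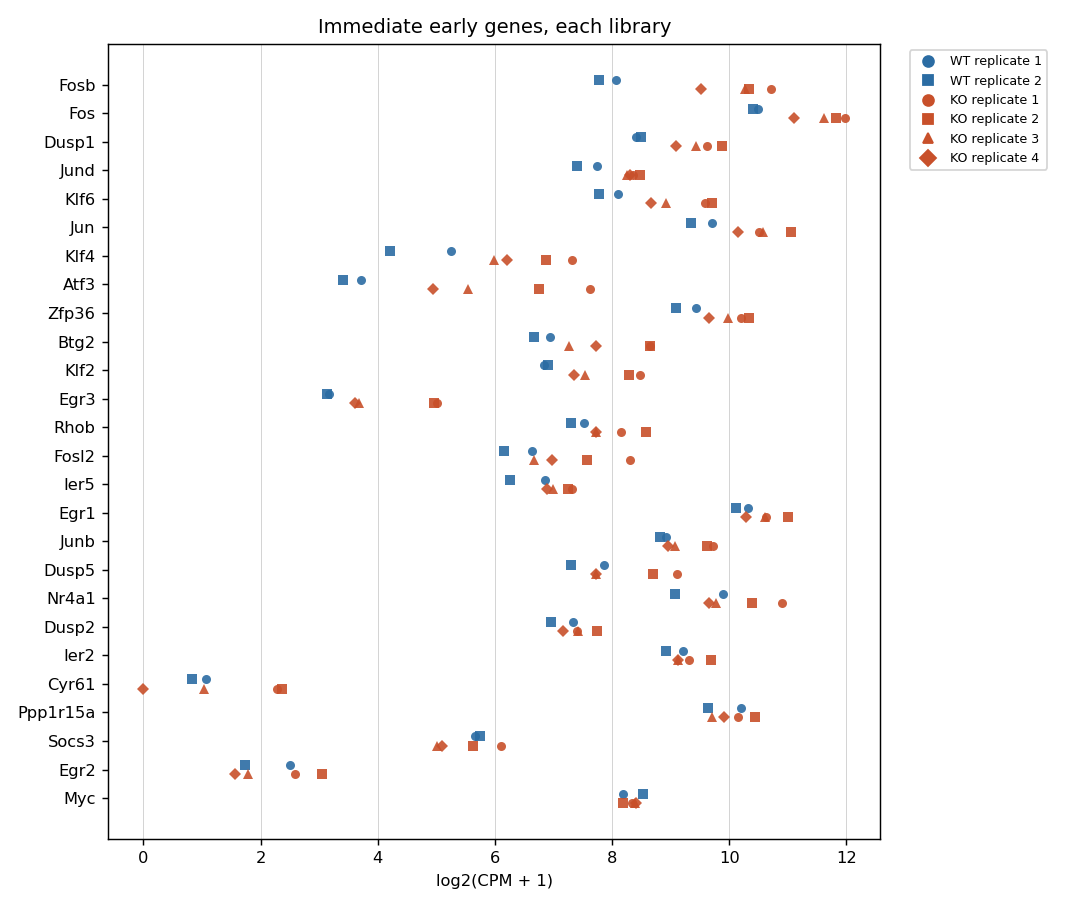
Expression of the 26 measured immediate early genes in each library on an axis of log2(CPM + 1), ordered from the smallest p at the top, with WT in blue and KO in orange. Most of the upper genes have all 4 KO libraries above both WT libraries, and KO replicates 1 and 2 tend to lie highest.

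Cytosolic ribosomal protein genes fell as a list, with 73 of 74 members below 0 and a median of -0.21 (camera adjusted p = 7.94e-11, adjusted p = 0.633 with an estimated correlation). Rpl34 and Rpl21 passed over all genes, DESeq2 called 4 and limma-voom 2, and 4 members passed when adjusted over the list alone, Rps18 and Rplp0 being the others. Rps18 starts at 33951999 on chromosome 17, near the called histocompatibility genes, and 13.1% of its total exon reads were placed uniquely. Rpl34 lies within 10 Mb of Elovl6. The ribosomal median was -0.12 without WT replicate 2 (camera adjusted p = 0.0127) and -0.32 without WT replicate 1 (camera adjusted p = 1.45e-15). HSC identity genes fell too, with 41 of 50 below 0 and a median of -0.24 (camera adjusted p = 2.44e-05, adjusted p = 0.633 with an estimated correlation). In edgeR 0 members passed over all genes, 17 had an unadjusted p under 0.05, DESeq2 called 1, limma-voom 0, and 1, Txnip, passed when adjusted over the list alone. The HSC identity score was 0.28 and 0.18 in WT, -0.47 in KO replicate 1, where B-lineage transcripts were highest, and 0.10, 0.07 and -0.16 in KO replicates 2 to 4. Its median was -0.16 without KO replicate 1 (camera adjusted p = 0.00221) and -0.14 without WT replicate 1 (camera adjusted p = 0.0129). Txnip, a thioredoxin inhibitor, was at 489 ± 24 CPM in WT (SD, n = 2) and 254 ± 60 CPM in KO (SD, n = 4). Vwf was at 170 ± 1.5 and 95.3 ± 29.3 CPM (log2 fold change -0.84, adjusted p = 0.372). Other HSC identity members, picked after their values were seen, lay near 0. On the log2 scale Mecom was at -0.01, Procr at 0.01, Hlf at 0.03, Meis1 at -0.09 and Fgd5 at -0.09. The fall of the list is thus not one of all its members. Markers of multipotent and lymphoid-primed progenitors rose (12 of 13 above 0, median 0.57, camera adjusted p = 0.00806, adjusted p = 0.633 with an estimated correlation). Of these 0 passed over all genes or over the list alone, 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0. Flt3, a receptor of early progenitors, was at 326 ± 25 CPM in WT and 559 ± 163 CPM in KO (adjusted p = 0.390). The progenitor score was 0.89 in KO replicate 1 and -0.16 to -0.07 in the other KO libraries. Without KO replicate 1 the median was 0.18 (camera adjusted p = 0.0679), and without WT replicate 1 it was 0.56 (camera adjusted p = 0.0638). B-lineage transcripts were also highest in KO replicate 1, where Pax5 reached 241 CPM against 26.0 to 88.1 CPM elsewhere.

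G2/M genes rose as a list (38 of 40 above 0, median 0.60, camera adjusted p = 7.76e-05, adjusted p = 0.688 with an estimated correlation), as did replication-dependent histones (29 of 31 above 0, median 0.37, camera adjusted p = 0.0197, adjusted p = 0.778 with an estimated correlation). For both, 0 members passed over all genes or over the list alone in edgeR, DESeq2 and limma-voom called 0, and 7 and 0 members had an unadjusted p under 0.05. G2/M scores were -0.65 and 0.01 in WT and ran from -0.36 to 0.91 in KO. Without WT replicate 1 the G2/M median was 0.31 (camera adjusted p = 0.356). It was 0.26 without KO replicate 1 (camera adjusted p = 0.0356) and 1.01 without WT replicate 2 (camera adjusted p = 6.34e-07). The histone median was 0.06 without WT replicate 1 (camera adjusted p = 0.579), 0.17 without KO replicate 1 (0.309), 0.16 without KO replicate 4 (0.299) and 0.72 without WT replicate 2 (5.38e-05). Nuclear genes of oxidative phosphorylation fell (49 of 60 below 0, median -0.17, camera adjusted p = 0.00152, adjusted p = 0.688 with an estimated correlation). Of these 0 passed either threshold, 4 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Without WT replicate 2 their median was -0.0010 (camera adjusted p = 0.920). It was -0.29 without WT replicate 1 (camera adjusted p = 2.1e-07) and -0.10 without KO replicate 3 (camera adjusted p = 0.0421).

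Megakaryocyte and platelet markers fell as a list (12 of 16 below 0, median -0.43, camera adjusted p = 0.00465, adjusted p = 0.633 with an estimated correlation). Selp, the platelet adhesion receptor P-selectin, was at 17.8 ± 0.1 CPM in WT and 4.27 ± 1.74 CPM in KO and was the single member past the threshold over the list alone. Over all genes edgeR called 0 of them, 3 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Without KO replicate 1 their median was -0.29 (camera adjusted p = 0.0637). Megakaryocyte scores were 0.32 and 0.24 in WT, and -0.78, 0.05, -0.16 and 0.33 in KO replicates 1 to 4. Mast cell, basophil and eosinophil markers passed downward (6 of 8 below 0, median -0.28, camera adjusted p = 0.0197, adjusted p = 0.633 with an estimated correlation), with scores from -2.29 in KO replicate 3 to 2.14 in KO replicate 4. Their median was above 0 without KO replicate 1 (0.17), KO replicate 2 (0.11), KO replicate 3 (0.14) or WT replicate 1 (0.08), while the test pointed down in each (camera adjusted p = 0.0679, 0.0288, 0.113 and 0.0638). It was -2.25 without KO replicate 4 and -0.99 without WT replicate 2, where the list passed (camera adjusted p = 0.000106 and 0.0499). Monocyte, macrophage and dendritic markers rose (17 of 17 above 0, median 0.70, camera adjusted p = 0.00357, adjusted p = 0.633 with an estimated correlation). Of these 0 passed over all genes, 2 had an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and 1, H2-Aa, passed over the list alone. H2-Aa starts at 34282744 on chromosome 17, near the called histocompatibility genes. The score of the monocyte, macrophage and dendritic list was 1.27 in KO replicate 4 and at most 0.13 in the other KO libraries. Without KO replicate 4 the median was 0.18 (camera adjusted p = 0.206), and without WT replicate 1 it was 0.66 (camera adjusted p = 0.0638).

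**Figure D4:**
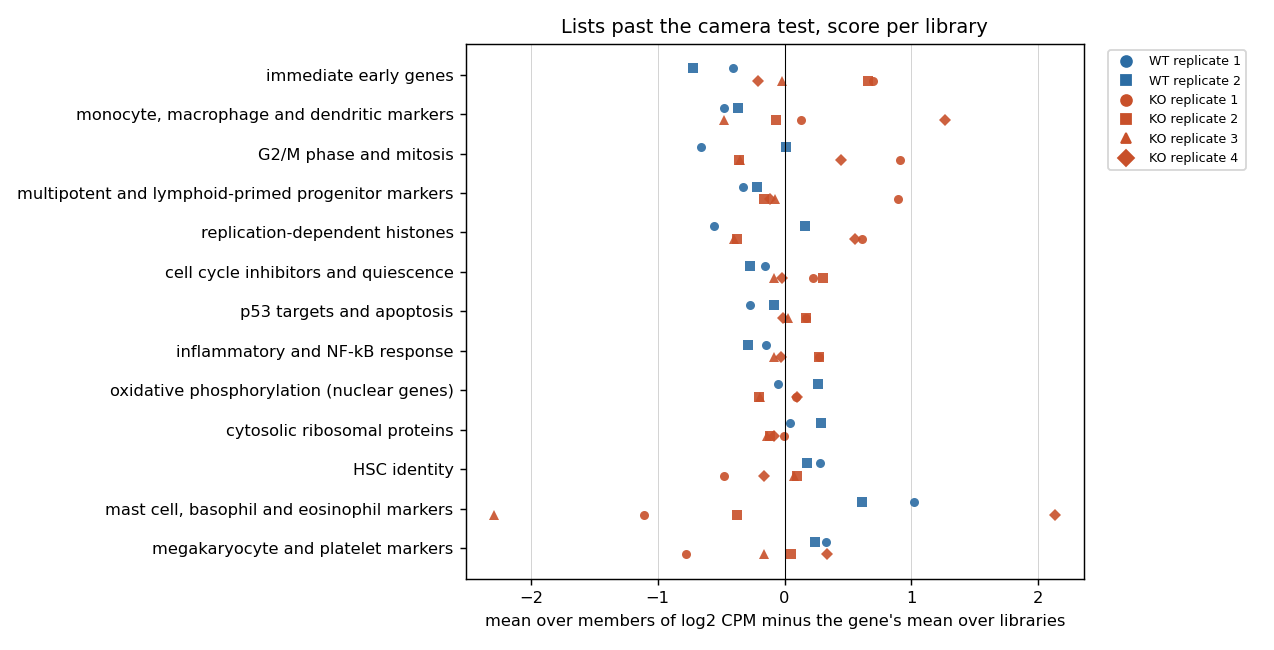
Score of each of the 13 lists past the camera test in each library, the mean over members of log2 CPM minus the gene's mean over libraries, with WT in blue and KO in orange. The immediate early list separates the groups, at -0.72 and -0.41 in WT and -0.21 to 0.70 in KO, while the mast cell list spreads from -2.29 to 2.14 within KO.

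Genes of fatty acid synthesis, elongation and desaturation, the pathway Elovl6 belongs to, did not pass as a list. Of these, 19 of 30 were below 0, with a median of -0.13 (camera adjusted p = 0.0818) and 0 members past the threshold over all genes or over the list alone in edgeR, 4 at an unadjusted p under 0.05, and 0 called by DESeq2 or limma-voom. Among the 33 lists tested, this one had the smallest p in the fry test (unadjusted p = 0.00443, adjusted p = 0.146), short of the threshold. Fads1, a fatty acid desaturase, was at 129 ± 3 CPM in WT (SD, n = 2) and 91.0 ± 11.8 CPM in KO (SD, n = 4) with an adjusted p of 0.390. Fatty acid oxidation and PPAR targets (median -0.16, camera adjusted p = 0.0765), sphingolipid and ceramide synthesis (median -0.02, 0.366), phospholipid remodelling (median -0.09, 0.576) and cholesterol synthesis (median 0.11, 0.950) did not pass either.

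Homing genes, chemokine receptors and integrins had 26 of 44 members above 0, a median of 0.05 (camera adjusted p = 0.606) and 0 members past either threshold in edgeR. Of these 7 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Cxcr4, the receptor that retains stem cells in marrow, was at 49.2 ± 8.1 CPM in WT (SD, n = 2) and 73.9 ± 14.1 CPM in KO (SD, n = 4), a log2 fold change of 0.58 (SE 0.21, adjusted p = 0.427). Pik3cg was at -0.13 (SE 0.17, adjusted p = 0.828), Rac2 at 0.11 (SE 0.17, adjusted p = 0.862), Itgb2 at 0.67 (SE 0.43, adjusted p = 0.630) and Itgam at 1.21 (SE 0.83, adjusted p = 0.665). PI3K, AKT and mTOR signalling (24 of 40 above 0, median 0.12, camera adjusted p = 0.325) and actin cytoskeleton and lamellipodia genes (31 of 49 above 0, median 0.06, camera adjusted p = 0.720) did not pass.

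The remaining lists did not pass at the preset correlation. Camera adjusted p-values, with medians in brackets, were 0.0615 for oxidative stress and ferroptosis (-0.09), 0.074 for S phase and DNA replication (0.18), 0.0944 for erythroid markers (0.66), 0.09997 for T, NK and innate lymphoid markers (0.57), 0.126 for stromal and endothelial markers (-0.38) and 0.126 for glycolysis and hypoxia (-0.11). They were 0.167 for mitochondrially encoded genes (0.17), 0.186 for B and plasma cell markers (0.90), 0.366 for interferon response (0.06) and 0.720 for heat shock and chaperones (-0.02). They were 0.767 for neutrophil and granulocyte markers (1.93) and 0.767 for the unfolded protein and integrated stress response (0.01). The heat shock median was below 0 while its mean (0.05) and its test pointed up, and the stromal and endothelial median was below 0, with its test, while its mean (0.12) was above. The phospholipid remodelling mean (0.02) was likewise above 0 and its median and test below. Without KO replicate 4 the neutrophil median was -0.05 and passed downward (camera adjusted p = 0.018), and the neutrophil score of KO replicate 4 was 3.29 against -2.41 to 0.79 in the other libraries.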

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

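All tests in the following were chosen after the results they address had been seen.

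The called genes H2-Ea-ps, Msh5, H2-Q2, H2-Q10 and H2-Bl lie close together on chromosome 17, and Gbp2b and Rpl34 lie on the chromosome of Elovl6. Induction of antigen presentation in KO cells is argued against by a median log2 fold change of -0.2204 over 9 genes of that pathway, the highest of which was Ciita at 0.50. Of these, Tap1, Tap2, Tapbp, H2-K1 and H2-D1 lie in the same region of chromosome 17. The others besides Ciita, B2m, Nlrc5 and Cd74, were at -0.28, 0.14 and 0.09. Class II genes not among the 9 went both ways, with H2-Aa at 0.70, H2-Ab1 at 0.45, H2-Eb1 at 0.15 and H2-DMb1 at -1.55. Reads that map to several places of mm10 are argued against as the cause for the first group. With unique exon reads alone each of its 5 genes passed, the lowest at a log2 fold change of 3.863. The size for H2-Q10 depends on such reads (2.65, adjusted p = 0.130, with multi-mapping exon reads included). Unique placement on mm10 cannot show whether reads of alleles that differ from mm10 were placed on these genes, which stays open. H2-Q10 had 0 intron reads in every library, against 401 counts in KO. H2-Q2, H2-Bl, H2-Ea-ps and Msh5 had intron reads in each KO library (at least 3, 5, 7 and 46). A chromosome 17 segment of another mouse strain in 1 genotype may account for the first group, but the scan does not decide it. At an unadjusted p under 0.01, bins from 25 to 30, 30 to 35 and 35 to 40 Mb had 9, 8 and 12 genes. Their permutation p was 0.0106, 0.0466 and 0.0001 against the fullest bin of the genome. Without H2 genes they had 9, 4 and 4, of which only the first was beyond chance for the fullest bin (permutation p = 0.0079). That bin lies outside the group and holds Dusp1 and Cdkn1a of the immediate early and p53 lists. Of the group, H2-Ea-ps and H2-Bl are annotated as polymorphic pseudogenes and H2-Q2, H2-Q10 and Msh5 as protein-coding. The strains are not given in the labels, and an effect of the genotype stays open too. Whether a segment was carried along with the Elovl6 allele is not decided by a count of genes near it. Within 10 Mb of Elovl6, 1 of 70 genes had an unadjusted p under 0.01, where shifted positions gave 1.78 on average (a share of 0.7556 of the shifts reached as many). That gene is Rpl34, which starts at 130726831 (unadjusted p = 6.1e-07, edgeR quasi-likelihood test). Only Gbp2b had a smaller p in the genome (4.5e-10), and the count gives no weight to how small a p is. Gbp2b, with its neighbours Gbp7 and Gbp3 at log2 fold changes of 0.62 and 0.53 (adjusted p = 0.372 and 0.390), lies outside that window. The called genes Lyrm7 and Gm2a also lie close together, starting at 54826866 and 55098115 on chromosome 11. Lyrm7 was higher and Gm2a lower in KO. An edge of the scan's bins at 55 Mb falls between them, and a segment there was not tested.

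Immediate early genes were higher in KO. RNA quality of KO replicates 3 and 4 as the cause is argued against by the list's median of 1.205 without these libraries. Mature myeloid or B-lineage cells in a single KO library are argued against by medians of 0.957 without KO replicate 4 and 0.7149 without KO replicate 1, both past the camera test. Handling of the cells before lysis could raise these genes and cannot be told apart from the genotype, since the order of collection is not given and the heat shock and chaperone list had a median of -0.02414 with members on both sides of 0. An effect of the genotype stays open and was not tested apart from handling.

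Iglc2, Iglv2 and Ighv10-1 were lower in KO. More B or plasma cells in the WT libraries are argued against by the 14 other measured genes of the B and plasma cell list, whose lowest median over all libraries and each library left out was 0.1692. Rearranged transcripts of a few cells per library are a candidate explanation that the counts leave open: 68.57% of 35 immunoglobulin V genes with at least 20 counts in some library had at least 80% of their CPM in 1 library, 10 of these 24 genes in WT replicate 1, 2 in WT replicate 2, 4 in KO replicate 1, 3 in KO replicate 2, 2 in KO replicate 3 and 3 in KO replicate 4. Of the genes to be explained, however, Ighv10-1 had 80.8% (81 and 19 counts in WT replicates 1 and 2), Iglv2 had 72.9% (133 and 49 counts), and Iglc2 had 434 and 269 counts in the WT libraries. A difference between the genotypes stays open.

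In 23 of 197 sets of 4 KO values, 1 library's gap to its nearest neighbour over the range was beyond Dixon's 95% critical value. Chance gives about 1 in 20 for independent, normally distributed sets. These sets are CPM values and scores of genes that vary together, so an excess over chance was not measured. KO replicate 4 stood apart in 14, KO replicate 1 in 6, KO replicate 3 in 3 and KO replicate 2 in 0. For KO replicate 4 the ratios were 0.8522 for Mmp8, 0.8357 for Mmp9, 0.8853 for Retnlg, 0.9059 for Fcnb, 0.8826 for Alas2, 0.9362 for Hba-a2 and 0.9073 for Hbb-bs. They were 0.8605 for Hdc, 0.9196 for Prg2, 0.896 for Slc27a4, 0.9213 for Eci2, 0.9221 for Hadh, 0.8935 for Ly6a and 0.8948 for mt-Nd4. For KO replicate 1 they were 0.9526 for Dntt, 0.9041 for Blnk, 0.8894 for Cxcl12 and 0.878 for Tmsb10, with 0.9159 for the score of the multipotent and lymphoid-primed progenitor list and 0.908 for that of the interferon response list. For KO replicate 3 they were 0.86 for H2-Bl, 0.8543 for Rplp0 and 1 for Ighv10-1, the last from a single count over the 4 KO libraries, which says nothing of that library. Reads on the ribosomal RNA-like gene CT010467.1, outside the main comparison, made up 22.03% of the mapped reads of KO replicate 3 and 27.95% of those of KO replicate 4, above both WT libraries.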

How the results depend on the processing

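The removal of KO replicates 3 and 4 together, unique exon reads and total exon reads were chosen after the data were seen. With DESeq2 size factors, a filter at a mean of 5 CPM, and unique or total exon reads, the count of called genes lay between 17 and 20. It was 87 with the DESeq2 test, 8 with limma-voom, 307 with no filter, 11 with glmTreat, 33 without KO replicates 3 and 4 together, and 34 with the replicate number as a block in 4 libraries. Leaving out 1 library at a time gave 2 to 30 genes, an Elovl6 log2 fold change of -1.32 to -0.95 and 7 to 15 lists. Where 1 WT library was left, it was assumed to vary like the KO libraries. Over the 15 alternatives run for it (glmTreat was not applied to it), Elovl6 stayed below 0 and passed the threshold only with no filter (-1.11, adjusted p = 0.0207), its adjusted p lying between 0.153 and 0.691 in the others. With an estimated correlation 0 lists passed and with fry 0, where camera at the preset correlation gave 13. Correlations of deviations from the group mean between libraries of the same number were -0.07 and -0.09. The deviations of the 2 WT libraries mirror each other (correlation -1), so these values cannot show whether the numbers pair the libraries. Of the called genes, Gbp2b kept its call in 16 of 16 alternatives, Iglc2 and Rpl34 in 15, and Itgb5 in 5. Over the named genes, 2309 comparisons kept direction and side of the threshold, 92 gained and 92 lost the call and 17 reversed, and over single lists these were 412, 28, 20 and 34. DESeq2 gave Hba-a2 and Prg2 no p, their largest Cook's distances of 26.8 and 33.4, in KO replicate 4, being above its cutoff of 18. The pseudocount alternative does not apply to counts and the sex covariate was not needed. Causes of the changes were not tested, apart from fewer libraries where some were left out. Depth limits genes with few counts.

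Values that reversed were as follows, all on the log2 scale. With limma-voom the unfolded protein list was at -0.071, Fcnb at -0.10 and Hdc at -1.18. With no filter the stromal list was at 0.61 and the heat shock list at 0.043. With the replicate block the erythroid list was at -0.025, the unfolded protein list at -0.039, the heat shock list at 0.12, Pik3cg at 0.031, Hdc at -0.99 and Kdm5d at 0.078. Without KO replicates 3 and 4 together the unfolded protein list was at -0.036, the heat shock list at 0.11, Pik3cg at 0.028, Hdc at -1.01 and Kdm5d at 0.078. With unique exon reads Atp5g2 was at 0.10, and with total exon reads the heat shock list was at 0.0033. With 1 library left out in turn, values ran from -0.13 to 0.25 for Eif2s3y, -1.46 to 1.19 for Hdc, -0.63 to 0.10 for Hspe1, -0.27 to 0.018 for Pik3cg and -3.41 to 0.81 for Prg2. List medians ran from -0.024 to 0.083 for actin cytoskeleton, -0.11 to 1.49 for erythroid, -0.21 to 0.051 for fatty acid oxidation, -0.085 to 0.15 for heat shock, -0.021 to 0.22 for interferon and -2.25 to 0.17 for mast cell genes. They ran from -0.048 to 3.98 for neutrophil, -0.13 to 0.045 for phospholipid, -0.11 to 0.56 for S phase, -0.081 to 0.072 for sphingolipid, -0.38 to 0.0026 for stromal and -0.066 to 0.084 for unfolded protein genes.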

Other observations

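Libraries of 1 genotype differed in transcripts of other blood cells. Hbb-bs, a globin gene of red cells, was at 661 CPM in KO replicate 4, at 46.8 to 104 CPM in the other KO libraries and at 8.53 and 31.8 CPM in WT (adjusted p = 0.408 for KO against WT), and Hba-a1, Hba-a2 and Alas2 were likewise higher in each KO library than in both WT libraries. Over the erythroid list, 13 of 19 members were above 0 and 6 below. Its scores overlapped, at -1.19 and -0.01 in WT and -0.71, 0.30, -0.63 and 2.26 in KO replicates 1 to 4. Mmp8, a neutrophil protease gene, was at 82.7 CPM in KO replicate 4, at 0.35 to 12.5 CPM in the other KO libraries and at 0.26 and 2.48 CPM in WT. Dntt, an enzyme of early lymphoid cells, was at 1567 CPM in KO replicate 1, at 273 to 335 CPM in the other KO libraries and at 228 and 263 CPM in WT, and the B-lineage gene Ebf1 at 136, at 18.6 to 45.5 and at 12.1 and 16.9 CPM.

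Reads across exon junctions of Elovl6 were 2 of 257 unique exon reads in WT (0.778%) and 30 of 241 in KO (12.4%). Over 8840 genes with at least 100 exon reads in each group, the median share was 27.4% in WT and 27.2% in KO, and 11 genes had a larger ratio of KO to WT share than Elovl6. The position of these junctions within the gene is not in the deposited table. The comparison was chosen after the values were seen.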
